A study of Homo sapiens with 6 samples.

How the data were processed

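RNA was measured by sequencing in 6 samples of primary human hepatocytes, 3 given a non-targeting siRNA pool (CTRL, samples 7, 8 and 9) and 3 given an siRNA pool against NREP (KD, samples 10, 11 and 12). Groups and sample numbers come from the sample titles. Per the labels' protocols, libraries were made with a stranded kit for polyadenylated RNA. Per the submitters' processing notes, kallisto and the GRCh38 build were used; their versions, the transcript set and the strand setting are not given in the sources used here. The deposited table holds 1 row per Ensembl gene with an estimated count per sample, and 19.5% of its values are not whole numbers. Estimated counts were rounded to whole numbers before testing.

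Of 63816 rows, 34597 had a count above 0 in some sample and 17184 passed edgeR's filterByExpr. The table includes genes on alternative haplotypes. Among the rows tested, 944 equal another row in all 6 samples, as do 31 of the called rows, so the counts of called genes include such copies. Symbols came from a gene name table that matched 57675 identifiers. Coordinates, exonic length, GC content and 3' UTR sequence came from GENCODE v29 on GRCh38, which holds 15994 of the tested genes, and 41 called genes are not in it.

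The comparison was fitted in edgeR 4.0.16 (R 4.3.3) with TMM factors and the quasi-likelihood F-test with robust dispersion. P-values were adjusted by Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p below 0.05. The design had the group as its only term. The groups share no sample number, so nothing pairs the samples. Fold changes are log2 KD over CTRL with their standard errors, and levels are CPM, counts over the TMM-scaled library total. For NREP an exact two-sided permutation test of log2 CPM was added, whose smallest p with 3 samples against 3 is 0.1. The labels do not say that the samples were separate cultures, so p-values measure the spread between these samples, which may be technical.

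Gene lists were fixed before the data were examined: 36 lists with 1086 distinct genes, all found in the table. The 34 lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over lists. Camera with an estimated correlation and fry were run beside it. The genes named were also set by rule beforehand. They are NREP, the 10 largest called changes in each direction with a mean CPM of at least 5 in the higher group, a named symbol and groups that do not overlap, the 3 largest called rises and falls in CPM, up to 4 called members per list and direction with the smallest p, and 21 genes fixed whatever their values. Some genes that the rule names are not reported here. Of the 111 genes named by the rule, 28 have another tested gene on the opposite strand within their span, 7 have one on the same strand, and 2 (CHORDC1 and PCK2) have a row equal to another.

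Library totals ran from 33361038 to 39575774 estimated counts. The fit was tested on simulated counts drawn from the real means, library sizes and dispersions with 200 changed genes among 17184. It recovered 32% of genes changed 1.5-fold and 65% of those changed 2-fold, and 5.77% of its calls were unchanged genes. A list shifted by 1.25-fold in the same simulation was called by camera and 0 other lists were. The simulation drew each gene independently, so it cannot show how often lists are called when genes vary together. Splits of the real libraries that mixed the groups called up to 10 lists.

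Heptamers in 3' UTRs were compared with fold changes from a fit in which a spline of log2 CPM on GC content and exonic length (5 degrees of freedom) was removed per library. Fold changes were then adjusted for 3' UTR length and GC content and limited to 1.5 in size. The 15982 heptamers with at least 100 carrier genes were tested over 13278 genes, with NREP left out. On permuted fold changes 0 heptamers passed, and a heptamer given a planted shift of -0.06 ranked 1. The siRNA sequences are not given in the sources used here. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used for this step.

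The alternatives planned before the data were examined were 3 other scalings, leaving out the 20 most abundant genes, 3 other filters, DESeq2 1.42.0, limma-voom with and without sample weights, no robust dispersion, other thresholds, unrounded counts, other list tests and each library left out in turn. A GC and length correction, a surrogate variable (sva 3.50.0), 1 row per set of equal rows, and leaving out carriers of 2 heptamers were added after the data were seen.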

Results

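The data are RNA sequencing of primary human hepatocytes, the main metabolic cell of the liver, pooled from 5 donors and grown on collagen. Cells received 100 nM of a non-targeting siRNA pool (CTRL) or of a pool against NREP (KD). They were starved in medium with 0.1% serum albumin for 16 h from 48 h after transfection. Each group has 3 samples. Total estimated counts were 39575774, 33361038 and 34317282 in CTRL 7, 8 and 9, and 37121323, 36299493 and 38769832 in KD 10, 11 and 12. The comparison asks which transcripts differ in hepatocytes depleted of NREP.

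NREP was lower in each KD sample than in each CTRL sample. NREP (ENSG00000134986, chromosome 5, 111662621 to 111997464, minus strand, GRCh38) had estimated counts of 457, 321 and 374 in CTRL 7, 8 and 9, and of 78, 87 and 106 in KD 10, 11 and 12. Its level was 10.6 ± 1.00 CPM in CTRL and 2.43 ± 0.236 CPM in KD (SD, n = 3 each), so that 22.9% of the control level was left. The log2 fold change was -2.13 with an SE of 0.12 (edgeR, adjusted p = 0.00222). An exact two-sided permutation test gave p = 0.1, the smallest value that 10 splits allow. NREP-AS1, annotated at the same locus, had a count of 0 in all 6 libraries.

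**Figure D1:**
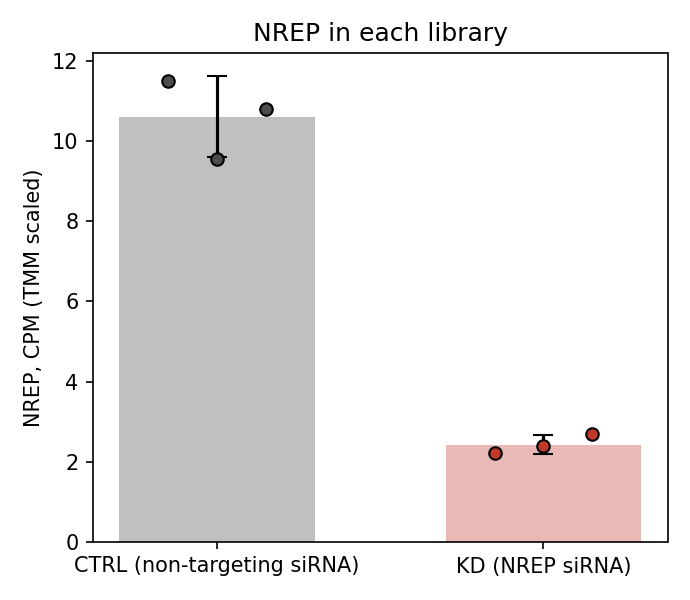
NREP level per library in TMM-scaled CPM. Points are single libraries, bars are group means and error bars are SD (n = 3 per group). The KD mean was 2.43 and the CTRL mean 10.6.

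Among called genes with a symbol and a mean of at least 5 CPM in the higher group, the largest rise was in IL20RB, a receptor chain for interleukins of the IL-20 family, which rose 2.94-fold from 4.86 ± 0.536 to 14.3 ± 1.47 CPM. MT1M, a metallothionein, rose 2.54-fold, TMCO1, a calcium channel of the endoplasmic reticulum, 2.34-fold, and CYP1A1, a target of the aryl hydrocarbon receptor, 2.25-fold. WIPI1, an autophagy protein, rose 2.21-fold. VSTM2L, TUBB6, IL22RA1 and ANGPTL8, also among the 10 largest rises, rose 2.19, 2.17, 2.16 and 2.13-fold. By change in level, the fibrinogen chain FGG rose from 836.5 ± 33.6 to 1065 ± 45.1 CPM, the tropomyosin TPM4 from 534.2 to 711.8 CPM, and the integrin ITGA5 from 390.6 to 565.4 CPM.

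After NREP, the largest falls under the same limits were in the long non-coding RNA LINC02009 (log2 fold change -1.82, SE 0.11), NIPSNAP3A (-1.44, SE 0.08) and SSR2 (-1.33, SE 0.11), a subunit of the translocon-associated protein complex. HIGD1A, a mitochondrial protein, fell from 507.5 ± 30.3 to 213.2 ± 9.61 CPM. UBD, a ubiquitin-like modifier, FGF19, a hormone that represses bile acid synthesis, and the transcription factor FOXO4 had log2 fold changes of -1.24, -1.24 and -1.22. MEX3A and the desmosomal cadherin DSC2 followed at -1.18 and -1.16. ANKRD1 fell from 1407 ± 32.5 to 868.2 ± 6.80 CPM, and ACLY, which makes cytosolic acetyl-CoA for lipid synthesis, from 470.2 ± 16.2 to 326.2 ± 20.3 CPM (log2 fold change -0.53, adjusted p = 0.0192). The annotated 3' UTRs of NIPSNAP3A, HIGD1A, FOXO4, DSC2, SSR2, MEX3A, ANKRD1 and ACLY carry GAAGGCT, CCCAAGA or both. These heptamers were picked for the low fold changes of their carriers. Both lie in NREP mRNA, as do 3875 of the 15982 heptamers tested. UBD and FGF19 carry neither GAAGGCT nor CCCAAGA, and LINC02009 was not searched. Among the 10 largest rises, TMCO1 carries CCCAAGA. TMCO1 and WIPI1 also carry CACATCA, a heptamer picked for the high fold changes of its carriers, as does DSC2 among the falls.

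**Figure D2:**
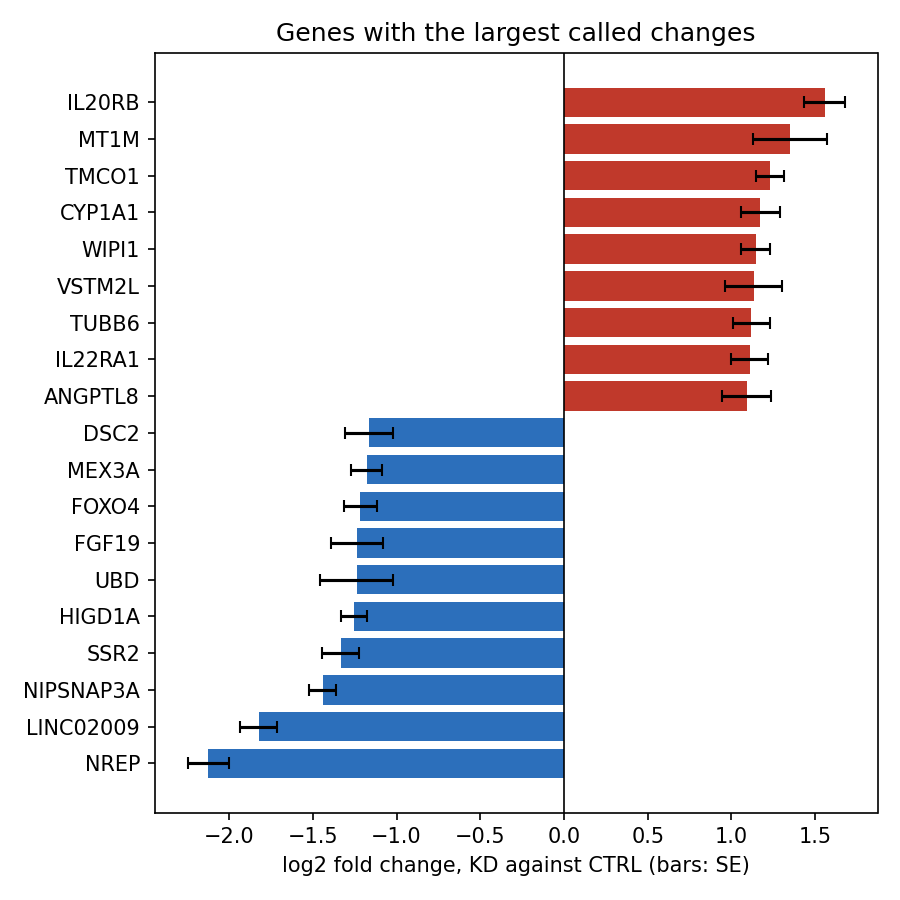
Log2 fold change of KD against CTRL for 9 of the 10 largest called rises and the 10 largest called falls among genes of at least 5 CPM in the higher group, with SE from edgeR (n = 3 per group). NREP has the lowest value, -2.13, and IL20RB the highest, 1.56.

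In all, 373 genes were higher and 320 lower in KD among 17184 tested, and 3915 had an unadjusted p below 0.05. The median called change was 1.51-fold among higher and 1.46-fold among lower genes. Of the called genes, 48 rose and 34 fell by more than 2-fold. KD replicate 10 stood apart from the other 5 libraries on the first principal component (45.6% of variance), at 58.8 against -21.7 to 6.0. On the second (20.4%) it lay among CTRL, at 12.9 beside 7.7 to 17.0, with KD 11 and 12 at -22.1 and -30.1. KD 11 and 12 had higher mean correlations with CTRL (0.9878 and 0.988) than with their own group (0.987 and 0.9848). Without CTRL replicate 7, CTRL replicate 8, CTRL replicate 9 or KD replicate 11 there were 6, 14, 8 or 14 higher genes and 10, 16, 11 or 14 lower ones, and without KD replicate 10 there were 1633 and 1671. Of the 90 called genes reported under the rule for names, 11 were called in all 6 of these fits: NREP, NIPSNAP3A, HIGD1A, LINC02009, SSR2, FOXO4, MEX3A, IL20RB, TMCO1, WIPI1 and PSAT1.

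Camera with the preset correlation called 5 lists. Of the 10 splits of the 6 libraries into 3 and 3, 6 called at least 5 lists, the real one included. A called list therefore does not by itself set this grouping apart. Genes of fatty acid oxidation and ketone synthesis rose as a list (camera, adjusted p = 0.000226, or adjusted p = 0.622 with an estimated correlation). Of 35 members tested, 5 rose, 0 fell and 28 had positive fold changes. CREB3L3, a liver transcription factor of the fasting response, rose 2.10-fold. The carnitine palmitoyltransferases CPT1A and CPT2 rose 1.35-fold and 1.30-fold. Adjusted over the list alone, 9 members were higher and 1 lower. Without KD replicate 10, 12 members were higher and 1 lower, and without CTRL replicate 7, 8 or 9 or KD replicate 11 there were 0, 2, 1 or 2 higher and 0 lower.

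The unfolded protein and integrated stress response list also rose (camera, adjusted p = 0.00066, or adjusted p = 0.578 with an estimated correlation). Of 36 members, 8 rose and 0 fell (19 and 2 adjusted over the list alone), among them STC2 (1.99-fold), the asparagine synthetase ASNS (1.92-fold), CHAC1 (1.96-fold) and the tryptophanyl-tRNA synthetase WARS1 (1.44-fold). Without KD replicate 10, 20 members were higher and 3 lower, and without CTRL replicate 7, 8 or 9 or KD replicate 11 there were 0, 1, 0 or 1 higher and 0 lower. Serine synthesis enzyme PSAT1, held by the one-carbon list, rose 1.92-fold (log2 fold change 0.95, SE 0.07). In that list of 45 genes, 9 rose and 0 fell (11 and 6 adjusted over the list alone), with TYMS at 1.56-fold, CBS at 1.5-fold and ALDH1L1 at 1.38-fold, while the list as a whole was not called (adjusted p = 0.32). Without KD replicate 10, 12 of its members were higher and 9 lower, and without CTRL replicate 7, 8 or 9 or KD replicate 11 it had 1 higher and 0 lower in each fit.

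Cholesterol synthesis and uptake rose as a list (adjusted p = 0.00277, or adjusted p = 0.578 with an estimated correlation). Of its 27 members 2 were called, among them INSIG1, a brake on sterol synthesis, at 1.29-fold, and 10 were higher and 1 lower when adjusted over the list alone. The called members numbered 13 higher and 1 lower without KD replicate 10, and 0 without CTRL replicate 7, 8 or 9 or KD replicate 11. In the lipid droplet list (adjusted p = 0.0308, or adjusted p = 0.858 with an estimated correlation), G0S2, an inhibitor of lipolysis, rose 1.96-fold, CIDEC 1.61-fold and HSD17B13 1.47-fold, whereas HSD17B11 fell by 0.50 on the log2 scale. Adjusted over the list alone, 5 of the 20 tested members were higher and 1 lower. Called over all genes, 6 were higher and 1 lower without KD replicate 10, and 0 were called without CTRL replicate 7, 8 or 9 or KD replicate 11. Its adjusted p was 0.055 after a GC and length correction and reached 0.069 without CTRL replicate 9. In fatty acid and triglyceride synthesis, ACLY fell and the other 25 members were not called, FASN among them (log2 fold change -0.38, SE 0.17, adjusted p = 0.227). Of its members 5 were higher and 4 lower without KD replicate 10, and 0 were called without CTRL replicate 7, 8 or 9 or KD replicate 11.

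The interferon response list was lower by camera (adjusted p = 0.000255, or adjusted p = 0.858 with an estimated correlation). Of 46 members tested, 37 had negative fold changes, with a median over the list of -0.28. With all 6 libraries edgeR called 0 members, and 19 were lower at an unadjusted p below 0.05. DESeq2 called 11 members lower and limma-voom 0. Limma-voom with sample weights called 28, counted without regard to direction. Its weights were 0.104, 5.99 and 0.616 for KD 10, 11 and 12, so KD 11 counted most. EdgeR called 1 higher and 6 lower without KD replicate 10, and 2 lower without CTRL replicate 8 or KD replicate 12. Fry, which does not compare the list with other genes, gave an adjusted p = 0.18.

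Bile acid genes moved in both directions and were not called as a list by camera (adjusted p = 0.443). FGF19 fell by 1.24 on the log2 scale, CYP8B1, the sterol 12-alpha-hydroxylase, by 0.66, the transporter SLC27A2 by 0.41 and the conjugating enzyme BAAT by 0.40, while AKR1D1 rose 1.53-fold. Fry gave this list an adjusted p = 0.0104. Called members numbered 6 higher and 6 lower without KD replicate 10, and 0 without CTRL replicate 7, 8 or 9 or KD replicate 11. CYP7A1 was not tested, with a largest count of 1. Among drug-metabolising enzymes, CYP1A1 and CYP1A2 rose (2.25 and 1.75-fold) and CYP3A4 and UGT2B4 fell, with log2 fold changes of -0.57 and -0.42. In gluconeogenesis and glycogen, GPT2, PCK2, IGFBP1 and TAT rose 1.71, 1.41, 1.40 and 1.37-fold and the liver glycogen synthase GYS2 fell by 0.39 on the log2 scale. The insulin list had 1 gene up, TRIB3 at 1.48-fold, and 1 down, FOXO4. The drug-metabolising, gluconeogenesis and insulin lists had 5, 5 and 7 higher and 8, 6 and 2 lower members without KD replicate 10. Without CTRL replicate 7, 8 or 9 or KD replicate 11 they had at most 1 higher and 1 lower each.

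Genes of the dedifferentiation list split evenly. ANXA1, VIM, TAGLN and CD44 rose 1.68, 1.48, 1.5 and 1.43-fold, and ANKRD1, KRT80, EPCAM and CD24 fell. Leaving out KD replicate 10 gave 7 higher and 7 lower members, and 0 were called without CTRL replicate 7, 8 or 9 or KD replicate 11. Hepatocyte identity genes had 1 rise, ITIH3, and 2 falls, FOXA1 and ITIH2, and ALB had a log2 fold change of 0.01 (adjusted p = 0.945), whose sign turned when libraries were scaled by their totals alone. Acute phase genes had 2 rises, FGG and KLKB1, and 3 falls, PLG, F13B and C9. Apolipoprotein genes had 3 rises, ANGPTL8, VLDLR and LIPC, and 1 fall, APOF. In the extracellular matrix list TIMP2, LOXL4 and TIMP3 rose and MMP7 fell, and in the TGF-beta list only TGFBR2 was called, at 1.30-fold. These 5 lists, from hepatocyte identity to TGF-beta, had 2, 7, 3, 9 and 4 higher and 8, 11, 6, 6 and 6 lower members without KD replicate 10, and 0 without CTRL replicate 7, 8 or 9 or KD replicate 11.

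Of the genes fixed in advance and reported here, CBS rose and ACLY fell, and 15 others were tested without a call. Leaving out KD replicate 10 gave 5 higher genes (CBS, CCN2, IRS2, SREBF2 and TGFB1) and 4 lower ones (ACLY, AHCY, BHMT and G6PC1), and 0 were called without CTRL replicate 7, 8 or 9 or KD replicate 11. With all 6 libraries, closest to the threshold were TGFB1 (log2 fold change 0.64, SE 0.14, adjusted p = 0.056), SREBF2 (0.31, SE 0.08, adjusted p = 0.0805) and BHMT, a betaine-using methyltransferase of methionine synthesis (-0.34, SE 0.09, adjusted p = 0.0908). SREBF1 had a log2 fold change of -0.02 (SE 0.10), whose sign turned with upper quartile scaling.

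Lists of other liver cells had few tested members and were not called. Of 8 macrophage markers, MRC1 fell from 4.6 to 2.26 CPM, and of 13 cholangiocyte markers EPCAM and CD24 fell. Of 13 stellate cell and fibroblast markers, ACTA2 and TAGLN rose 1.6 and 1.5-fold. With all 6 libraries edgeR called 0 of 10 endothelial and 0 of 3 lymphocyte markers, with 5 and 1 called by limma-voom with sample weights and 0 by DESeq2 or limma-voom. At an unadjusted p below 0.05, 1 endothelial marker was higher and 4 lower, and 1 lymphocyte marker was higher. Without KD replicate 10, 1 endothelial marker was higher and 2 lower, and the macrophage, cholangiocyte and stellate lists had 1, 1 and 4 higher and 1, 4 and 0 lower. Those 3 lists had 0 called without CTRL replicate 7, 8 or 9 or KD replicate 11. Of the red cell and platelet markers 0 passed the filter.

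GAAGGCT and CCCAAGA were picked among 15982 heptamers because their carriers were shifted lowest, by z, in the GC- and length-corrected fit of this same comparison. An excess of their carriers among lower genes therefore restates that choice. With adjustment over all 15982 heptamers, 15 were lower and 3 higher at an adjusted p below 0.05, GAAGGCT and CCCAAGA among the lower ones. The lower ones include overlapping heptamers such as CCAAGAA and AGAAGGC, and unlike ones such as TTATTTA and TGGGGGT. On permuted fold changes 0 passed. That single shuffle over genes also removes any shared behaviour of genes, so it cannot show what picking gives in these data. The heptamer test treats genes as independent replicates, which they are not. Of the 273 lower genes with a searched 3' UTR, NREP aside, 48.4% carried GAAGGCT or CCCAAGA, against 17.2% of the higher genes and 22.8% of genes not called. Draws of genes not called, matched on 3' UTR length, had mean shares of 25.9% for the lower and 20.7% for the higher genes. Other carriers named above include the lower genes CYP8B1, HSD17B11, KRT80, MRC1 and APOF and the higher genes HSD17B13, TIMP2, TIMP3, VLDLR and TAT. Presence in NREP mRNA is common, at 3875 of the 15982 heptamers tested. There GAAGGCT lies at chromosome 5, 111735437 to 111735443, in the coding sequence of 16 of 17 annotated coding transcripts, and at 111756219 to 111756225 in the 5' UTR of 1. CCCAAGA lies at 111730945 to 111730951, in the coding sequence or 3' UTR of 14, and at 111755787 to 111755793, in the 5' UTR of 16.

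**Figure D3:**
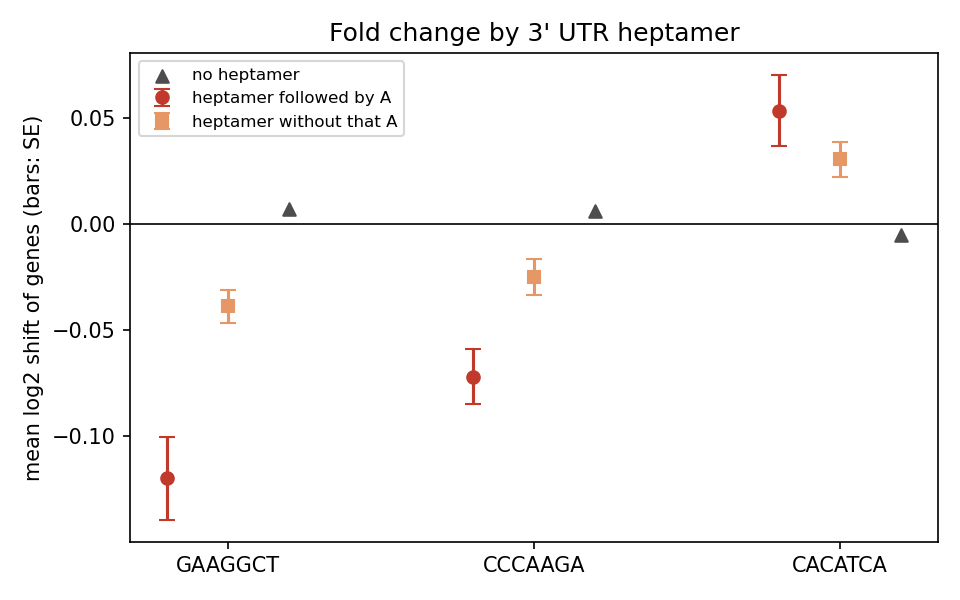
Mean log2 shift of genes by 3' UTR heptamer, for the lowest pair of heptamers and the highest one, with SE over genes. The lowest point is GAAGGCT followed by A, at -0.12. The heptamers were picked from these same shifts, so their distances from 0 as drawn, not adjusted for the picking, are no test. Genes are not independent replicates.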

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

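The GC and length correction, the surrogate variable, 1 row per set of equal rows and leaving out carriers of the heptamers were chosen after the data were seen. Unless fewer genes or samples entered a fit, the cause of a change was not tested. NREP kept its direction and its call in every alternative fitted, with log2 fold changes from -2.2 to -2. All 693 called genes kept their sign without each of the 6 libraries in turn and with the correction. The KD and CTRL values of all 693 did not overlap, so leaving out 1 library could hardly turn a sign. For the 104 other named genes reported, 135 values below 0 and 222 above 0 under the alternatives lost the call, and 15 and 21 gained it. DESeq2 called 671 of the 693 genes as well. In the simulation 32% of 1.5-fold changes were recovered, so that changes of this size can be missed at this group size. The share depends on how many genes change. The simulation called 104 genes and the data 693, so the 32% need not hold for these 6 libraries. No paired analysis was possible because the groups share no sample numbers. Values in brackets after a list are its adjusted p.

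Scaling by library totals alone turned the sign of ALB (log2 fold change -0.01). Upper quartile factors turned the direction of hypoxia (0.979). It turned the sign of SREBF1 (log2 fold change 0.0032) and IRS1 (log2 fold change 0.01). No filter on low counts gave 8 called lists. It also called p53 targets and apoptosis (0.0372), nuclear-encoded oxidative phosphorylation (0.0226) and mitochondrially encoded genes (0.033). A mean CPM of at least 5 gave 11 called lists. It also called NF-kB and inflammatory cytokines (0.0402), p53 targets and apoptosis (0.0356), cell cycle (0.0338), nuclear-encoded oxidative phosphorylation (0.036), mitochondrially encoded genes (0.0402) and stellate cells and fibroblasts (0.0402). It turned the direction of drug-metabolising P450 and conjugation enzymes (0.991) and acute phase and coagulation (0.991). DESeq2 gave 785 higher and 739 lower genes and 9 called lists. It also called NF-kB and inflammatory cytokines (0.0446), p53 targets and apoptosis (0.0307), nuclear-encoded oxidative phosphorylation (0.0307) and mitochondrially encoded genes (0.0315). Limma-voom gave 8 called lists. It also called p53 targets and apoptosis (0.0343), nuclear-encoded oxidative phosphorylation (0.0343) and mitochondrially encoded genes (0.0343). Limma-voom with sample weights weighted KD 10, 11 and 12 at 0.104, 5.99 and 0.616, and CTRL 7, 8 and 9 at 2.3, 0.899 and 1.26. Its KD side thus rested mostly on KD replicate 11. This fit gave 3307 higher and 3364 lower genes and 8 called lists. It also called p53 targets and apoptosis (0.0155), mitochondrially encoded genes (0.0251) and, as lower, cytosolic ribosomal proteins (0.0059). It turned the direction of fatty acid and triglyceride synthesis (0.705), insulin and PI3K-AKT signalling (0.851), urea cycle and amino acid catabolism (0.982), cytosolic ribosomal proteins (0.0059) and hypoxia (0.987). It turned the sign of ALB (log2 fold change -0.01) and IRS1 (log2 fold change 0.07). A threshold of 0.01 gave 29 higher and 30 lower genes. A threshold of 0.10 gave 800 higher and 681 lower genes. A test against a fold of 1.2 gave 49 higher and 44 lower genes. An estimated correlation gave 0 called lists. It no longer called cholesterol synthesis and uptake (0.578), fatty acid oxidation and ketogenesis (0.622), lipid droplet and lipolysis (0.858), interferon response (0.858) and the stress response (0.578). Fry called bile acid synthesis and transport (0.0104) and p53 targets and apoptosis (0.00729). It no longer called lipid droplet and lipolysis (0.0856) and interferon response (0.18). Camera on ranks gave 8 called lists. It also called NF-kB and inflammatory cytokines (0.0444), nuclear-encoded oxidative phosphorylation (0.0244) and mitochondrially encoded genes (0.0354). It turned the direction of hypoxia (0.927). Lists without shared members turned the direction of fatty acid and triglyceride synthesis (0.994), hypoxia (0.994) and cholangiocytes (0.589). The GC and length correction gave 761 higher and 734 lower genes. It also called hepatocyte identity (0.0213), p53 targets and apoptosis (0.0137) and mitochondrially encoded genes (0.0143). It no longer called lipid droplet and lipolysis (0.055). It turned the direction of apolipoproteins and lipoprotein handling (0.974), urea cycle and amino acid catabolism (0.974) and hypoxia (0.821). It turned the sign of MAT1A (log2 fold change -0.01) and IRS1 (log2 fold change 0.01). The surrogate variable gave 2222 higher and 2452 lower genes. It also called p53 targets and apoptosis (0.0187) and mitochondrially encoded genes (0.0499). It turned the direction of fatty acid and triglyceride synthesis (0.867), urea cycle and amino acid catabolism (0.952), cytosolic ribosomal proteins (0.235) and hypoxia (0.952). It turned the sign of ALB (log2 fold change -0.01) and IRS1 (log2 fold change 0.05). Leaving out carriers of the 2 heptamers gave 169 lower genes. It turned the direction of fatty acid and triglyceride synthesis (0.658), extracellular matrix (0.985) and urea cycle and amino acid catabolism (0.765). It turned the sign of ALB (log2 fold change -0.01).

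The fits that leave out 1 library each gave 6 to 1633 higher genes, 10 to 1671 lower genes and 4 to 10 called lists. Called genes numbered 16, 30 and 19 without CTRL replicate 7, 8 or 9, and 3304, 28 and 810 without KD replicate 10, 11 or 12. Adjusted p over these fits ran as follows for lists whose call or direction changed, namely fatty acid and triglyceride synthesis 0.641 to 0.986, lipid droplet and lipolysis 0.0106 to 0.069, insulin and PI3K-AKT signalling 0.564 to 0.986, extracellular matrix 0.0633 to 0.687, acute phase and coagulation 0.704 to 0.942, p53 targets and apoptosis 0.0142 to 0.116, NRF2 and antioxidant genes 0.0262 to 0.869, urea cycle and amino acid catabolism 0.476 to 0.918, nuclear-encoded oxidative phosphorylation 6.55e-05 to 0.329, mitochondrially encoded genes 0.00302 to 0.329, cytosolic ribosomal proteins 3.61e-06 to 0.687, hypoxia 0.78 to 0.958 and small RNA pathway and RNA silencing 0.0161 to 0.618. Cytosolic ribosomal proteins were called lower without KD replicate 10 and higher without KD replicate 12. Log2 fold changes in these fits were SREBF1 -0.09 to 0.06, ALB -0.03 to 0.05 and IRS1 -0.15 to 0.13.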

Other observations

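The tests of the called lists against the GC and length trend and of sites followed by A were chosen only after the results were seen, as was leaving out carriers of the heptamers.

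Several lists that the report leaves out held small changes. In the NRF2 list, NQO1 and AKR1B10 rose 1.56 and 1.37-fold and 27 of 29 members were not called. The immediate early genes KLF4 and MYC rose 1.39 and 1.26-fold. In glycolysis, the transporter SLC16A3 and the glucokinase regulator GCKR rose 1.63 and 1.29-fold and PFKFB1 fell by 0.56 on the log2 scale. The p53 target BTG2 rose 1.42-fold, the heat shock genes CHORDC1 and HSPA4 fell by 0.50 and 0.35 on the log2 scale, and the hypoxia gene ADM fell by 0.56. In the urea cycle list TAT and NAGS rose 1.37 and 1.46-fold and OTC fell by 0.51. TYMS was the 1 called cell cycle gene. Leaving out KD replicate 10 gave the NRF2, immediate early, glycolysis, p53, heat shock, hypoxia, urea cycle and cell cycle lists 4, 4, 5, 11, 2, 3, 5 and 4 higher and 4, 2, 4, 3, 3, 4, 8 and 0 lower members. Without CTRL replicate 7, 8 or 9 or KD replicate 11 each of these 8 lists had 0 called. No member of the NF-kB, small RNA pathway, nuclear-encoded oxidative phosphorylation, mitochondrially encoded or cytosolic ribosomal lists was called by edgeR with all 6 libraries, and their camera adjusted p-values were 0.0737, 0.0881, 0.0634, 0.0634 and 0.419. At an unadjusted p below 0.05 these lists had 6, 1, 4, 3 and 0 members higher and 2, 3, 2, 0 and 0 lower. DESeq2 called 3, 1, 0, 1 and 0 members, limma-voom 0 in each, and limma-voom with sample weights 12, 4, 15, 5 and 9. Without KD replicate 10, edgeR called 5, 0, 1, 2 and 0 higher and 2, 3, 6, 0 and 15 lower. The hypoxia list and the acute phase list had positive means, 0.01 and 0.03, and a downward camera direction.

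The first pattern is the set of genes other than NREP that are lower with the NREP siRNA pool. One hypothesis is that part of them respond to the siRNAs' own seed matches in 3' UTRs and not to the loss of NREP. A test set beforehand did not decide it: 7 of the 20 lowest heptamers lie in NREP mRNA, against a mean of 5.42 and a 95th percentile of 9 in 10000 matched draws. A later comparison of carriers of the lowest pair, GAAGGCT and CCCAAGA, with and without a following A gave -0.0472 as the smaller difference, but it is void as a test. The pair was picked on the same fold changes, and with the A each ends in another of the 20 lowest heptamers, AAGGCTA or CCAAGAA. For CACATCA, the highest heptamer, the shift was 0.0534 with the A and 0.0304 without it (permutation p = 0.0903). That contrast is void for the same reasons. CACATCA was picked on these fold changes, and with the A it ends in ACATCAA, another of the 20 highest heptamers. Whether any of these heptamers is a seed site stays open, since the siRNA sequences were not used here. A seed effect and a response to NREP loss cannot be told apart for these genes.

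The second pattern is that more genes pass the threshold without KD replicate 10. GC content and exonic length explained a share of 0.213 of the variance of that library's deviation from the other KD libraries, between the bounds of 0.2 and 0.5 set beforehand, so that a trend of this kind as the cause cannot be told apart from other differences of this library. That library had 9.94% of its counts in mitochondrially encoded genes, against 7.42% to 8.4% in the others. Its deviation from the mean of all 6 libraries had Spearman correlations across genes of 0.44 with GC content and -0.45 with length. With GC content CTRL 9 had -0.45 and CTRL 7 -0.38, and with length the other libraries had 0.02 to 0.28. Deviations from a mean of all 6 libraries sum to 0 per gene, so a trend in 1 library shifts the others oppositely. Against the rest of its own group, the explained share was 0.007, 0.045 and 0.026 for CTRL 7, 8 and 9. It was 0.058 and 0.158 for KD 11 and 12, where the comparison includes KD replicate 10. The correction gave 1495 called genes against 3304 without the library, and 642 of the 693 called genes stayed called. No biological explanation was tested, since the labels describe the KD samples alike.

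The third pattern is the called lists. Fold changes followed GC content across genes (Spearman rho 0.402, and 0.005 after the correction), so a GC and length trend could move lists. Leaving out carriers of either heptamer still called all 5 lists. After the GC and length correction 4 of the lists, fatty acid oxidation, interferon, stress response and cholesterol, were still called in the same direction. Their calls therefore did not rest on that trend as fitted. These 4 were grouped apart from the lipid droplet list after the results were seen, and splits that mixed the groups also called lists. No cause of the calls follows. For the lipid droplet list the mean above other genes was 0.199 before and 0.138 after, and its call ended at an adjusted p = 0.055, within a range over its alternatives of 0.0106 to 0.858. A response to NREP loss remains open for all 5.

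The 6 libraries can be split 10 ways into 3 and 3, too few for a share under 0.05. For genes, 1 split gave as many calls as the real one, itself, with 693, and the highest of the others gave 1. For lists, 6 splits gave at least the 5 lists of the real one, itself included, and the highest of the others gave 10.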
